A study of Drosophila melanogaster with 48 samples.

How the data were processed

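Whole brains of adult female Drosophila melanogaster were profiled by sequencing of rRNA-depleted RNA, with 48 libraries in 23 groups. Per the labels, each sample held about 15 brains of flies 3 to 5 days old kept at 25 °C with 12 h of light, and libraries came from 150 to 250 ng of RNA with a stranded kit. The pan-neuronal driver C155-Gal4 expressed a short hairpin RNA against GFP (the control, n = 4) or against a gene for an RNA-binding protein (22 lines, n = 2 each, 20 targeted genes). The labels do not state that replicates are separate crosses or cultures beyond their numbers.

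Per the submitters' processing notes, the tools were Trim Galore 0.4.5, STAR 2.5.4b, SAMtools 1.4, RSEM 1.2.30 and DESeq2 1.20.0 with genome build dm6, and the notes give these tools no roles. Per the file headers, the gene tables hold the deposited expected counts, which are estimated read or fragment numbers per gene that are not scaled to depth. They also hold the deposited TPM, scaled within each library by the authors, which was used for 1 alternative only. Per the file headers, the editing tables hold the deposited counts of reads with A and of reads with G at each listed site. They also hold the editing level as a deposited fraction, which was recomputed from the read counts with a largest difference of 0.0005. How sites were chosen, how bases were filtered and whether counting used the strand are not stated. Reads shared between near-identical genes, such as the Hsp70 and Jon65A genes, were divided by the authors' counting, so values of single members are uncertain. The same holds for antisense and overlapping genes, since use of the strand in counting is not stated.

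The gene tables held 17453 gene identifiers, of which 17179 were matched to a symbol, 199 of them by transcript identifier. The total expected count per library ranged from 5289480 to 13252279. The editing tables listed 13091 sites, of which 2345 had at least 20 reads in every library. The median number of reads per listed site ranged from 9 to 22 between libraries. Gene positions are from the reference annotation in dm6 coordinates. Site positions are printed as deposited, and neither the base at a position nor whether positions count from 0 or 1 could be checked without the genome sequence. Sites were assigned to features with the same annotation. Editing levels are given as percent, the mean of replicates ± SD. Differences in percentage points at single sites are between the edited shares of the pooled reads of each group, so they can depart from the difference of the means. Intervals and errors cover counting error and spread between these libraries, not errors in the list of sites.

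Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, filterByExpr, 10248 genes kept) in 1 fit of all 48 libraries with 23 groups and a contrast of each line with GFP. Adjusted p values are Benjamini-Hochberg values over all genes tested in a line, and genes under 0.05 are called changed. The standard error of a log2 change is its size divided by the square root of the F statistic. CPM values are counts scaled by the TMM-normalized library size. Because all 22 lines share 4 controls and have 2 libraries each, all groups share 1 estimate of spread.

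Editing was tested at each site with a quasi-binomial likelihood ratio F test of edited against unedited reads. The dispersion came from all groups, was moderated across sites with limma 3.58.1 and was not allowed below 1. A site was tested in a line when it had at least 20 reads in each of the 6 libraries and at least 1% edited reads over these libraries pooled, with Benjamini-Hochberg adjustment within each line and the same 0.05 threshold. The mean editing level of a library is the mean over the 2345 sites read at least 20 times in all 48 libraries. Its difference from GFP was tested with a two-sided exact permutation test over 15 splits of 2 against 4 libraries, for which the smallest possible p is 0.0667.

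The 2 pairs of controls, replicates 1 and 2 and replicates 3 and 4, were found to differ, as the report states. Each count is therefore also given for the genes or sites called in the same direction with all 4 controls, with controls 1 and 2 alone and with controls 3 and 4 alone. These are called all 3 control sets below, and this criterion was chosen after seeing the data.

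In all, 24 gene lists were written before the data were examined, as were the main tests, their thresholds and the rule for named genes. The lists were screened RNA-binding proteins, pan-neuronal genes, synaptic release, transmitter synthesis and transport, voltage-gated channels, ligand-gated receptors, neuropeptides, circadian clock, immune peptides, antiviral RNAi, heat shock, stress and apoptosis, glia, photoreceptor, fat body, muscle, hemocyte, trachea, dosage compensation, markers of genetic background, splicing factors, cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes. No gene of the last list was among those tested, so 23 lists were tested in each line. List members were tested with camera of limma at a preset correlation between genes of 0.01, with adjustment over the lists within a line. Camera with an estimated correlation and fry were the alternatives. The fry result depends slightly on the order of the groups, which was alphabetical with capitals first. A second family of cuticle genes was defined by symbol for 1 test of the control pairs.

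Genes were named by rule. For Adar and Zn72D, with 2 lines each, these are the targeted gene, the 10 largest mean changes in each direction among genes called in both lines, and the 3 largest in each line alone. For each of the other 18 lines they are the targeted gene and the 2 largest changes in each direction. Up to 4 called members were named of a list that passed its test or had at least 3 called members. A named gene had an average log2 CPM of at least 1 and both replicates of the line beyond all 4 controls, except list members. Adar, Zn72D, Fmr1 and mle were named in any line where called. Sites were named likewise, with 10 falls and 5 rises common to both lines of a target, 2 in each direction elsewhere, and every tested site in the Adar gene for the Adar and Zn72D lines. The report prints mainly those named genes and sites that were called with all 3 control sets. A gene with no count in a whole group has no defined log2 change and is given as a bound from 3 counts over that group or without a size.

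Alternatives chosen in advance were RLE normalization, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of a line and the controls alone, the replicate number as a block, each pair of controls alone, and leaving out each library in turn. For editing they were read minimums of 10 and 50, no minimum level, a Fisher exact test on pooled reads, and a dispersion from the line and controls alone. For the mean editing level they were read minimums of 10 and 50 and reads pooled over sites. For the relation of Adar transcript and mean editing, across groups that do not target Adar, they were the deposited TPM, single libraries and a read minimum of 10. Chosen after seeing the data were the count with all 3 control sets, the list tests with each pair of controls, the count of sites that depend on Adar, and the relation without the Zn72D lines, with all controls and with controls 1 and 2 only.

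A site was said to depend on Adar when its pooled level in Adar_VDRC7763 was below 50% of both the control level and the level over the 44 libraries not targeting Adar. This measure was tightened after a first result: the first form compared only with the 44 libraries, and gave 83.8% of the sites higher in the 18 other lines as dependent against 69.1% with the final form.

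Comparisons share control libraries, so overlaps between lines are given beside 8 simulations of unchanged groups sharing the controls, which hold no real changes and no difference between the control pairs, beside the number for independent lists, and with the controls split between the lines. The tests were tested on simulated data built from the Zn72D line and GFP with 200 genes or sites changed. Changed genes for the count test had an average log2 CPM of at least 1, and changed sites had levels in the middle of the scale. Tested sites in the Zn72D line had median control levels of 6.46% in 3' UTRs and 12.15% in coding exons. Recovery at sites of low level was therefore not simulated. The count test on 10248 genes recovered 100% of genes raised by 2 on the log2 scale, 61.3% of those raised by 1 and 48.3% of those raised by 0.60. It recovered 84.4%, 73.7% and 34.4% of those lowered by 2, 1 and 0.60, and 4.86% of its calls were false. The editing test on 2494 sites recovered 66.7% of falls and 55.6% of rises of 20 percentage points, 14.8% and 14.3% at 10 points, and 3.03% and 0% at 5 points, with 3.64% of calls false. The planted list passed camera, and 1.5% of 200 unchanged lists were under 0.05. Genes and sites in these simulated data varied independently, with no difference between the control pairs. The rates of false calls therefore do not cover correlated genes or that difference. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Raw reads, protein levels and genotypes were not used here.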

Results

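RNA of adult female fly brains was measured in 48 libraries: 4 from flies with a pan-neuronal hairpin against GFP, which serve as the control, and 2 from each of 22 knockdown lines. The lines target 20 genes for RNA-binding proteins, with 2 lines each for Adar, the adenosine deaminase that edits A to I, and for Zn72D, a zinc finger protein known for a role in splicing of mle transcripts. The lines are named after their target, with the stock for Adar_BDSC28311, Adar_VDRC7763 and Zn72D_BDSC55635, while the other Zn72D line carries no stock name. Libraries held 5289480 to 13252279 expected counts, with a median of 7873484. Of 13091 listed editing sites, 56.9% lay in introns, 24.2% in coding exons and 13.7% in 3' UTRs. Values are means ± SD of 2 libraries for a line and of 4 for GFP, log2 changes are given with their standard error (SE), and positions are in dm6.

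The 4 controls did not form 1 group. Control replicates 3 and 4 had 2455 genes higher and 2354 lower than replicates 1 and 2 among 10248 tested with edgeR, and 31 of 2594 editing sites were higher and 27 lower. On the first principal component of gene expression, which held 32.4% of the variance, GFP 3 and GFP 4 lay at 79.2 and 83.9, with Adar_VDRC7763 at 81.1 and 47.0 and Zn72D_BDSC55635 at 83.2 and 91.7. Mean fragment length was 252 and 263 bases in GFP 1 and 2 and 225 and 213 in GFP 3 and 4. Between the pairs, 68 of 85 ribosomal protein genes were lower in controls 3 and 4, 14 of 19 muscle, 9 of 9 tracheal and 16 of 24 glial list genes were higher, and 18 of 24 voltage-gated channel genes were lower. Among other lists, synaptic release had 14 higher and 4 lower of 25, neuropeptides 4 and 11 of 33, and oxidative phosphorylation 42 and 4 of 71. Stress and apoptosis had 11 higher and 0 lower of 23, and hemocyte 3 and 10 of 14. Splicing factors had 1 higher and 9 lower of 30, and dosage compensation 0 and 6 of 8. These are counts without a list test, and 4809 of all 10248 genes were called between the pairs. The labels name no batch, so each line is compared with all 4 controls and with each pair.

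**Figure D1:**
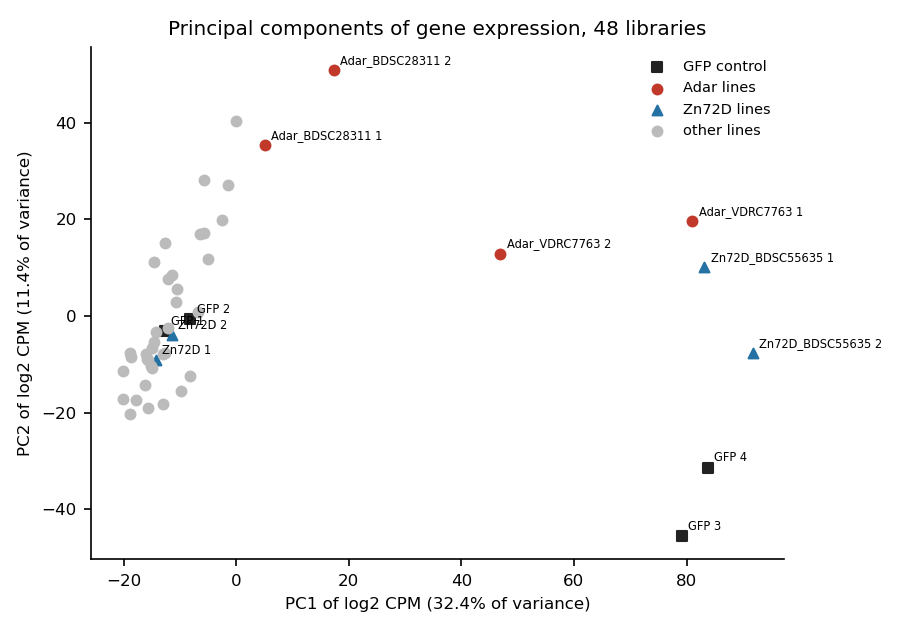
First and second principal component of log2 CPM for 48 libraries, as points coloured by group with the replicate number beside the GFP, Adar and Zn72D libraries. GFP 3 at 79.2 and GFP 4 at 83.9 lie far from GFP 1 and 2 on the first component, near the Adar_VDRC7763 and Zn72D_BDSC55635 libraries.

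The first question was whether each hairpin lowered its target. The targeted gene was lower in 22 of 22 lines, with both replicates below all 4 controls in each. Transcript levels ranged from 10.9% of control for CG4612 to 54.8% for Hrb87F, with a median of 35.3%. Adar (FBgn0026086) fell from 499 ± 82.2 CPM to 162 ± 12.4 CPM in Adar_BDSC28311 (log2 change -1.63, SE 0.22, edgeR adjusted p = 0.000108) and to 156 ± 16.9 CPM in Adar_VDRC7763 (log2 change -1.68, SE 0.23, edgeR adjusted p = 3.98e-05). Zn72D (FBgn0263603) fell from 120 ± 26.7 CPM to 61.1 ± 5.24 CPM in the Zn72D line (log2 change -0.97, SE 0.12, edgeR adjusted p = 8.4e-06) and to 28.2 ± 0.51 CPM in Zn72D_BDSC55635 (log2 change -2.09, SE 0.13, edgeR adjusted p = 1.29e-11). All 22 targets were also called lower with controls 1 and 2 alone and with controls 3 and 4 alone. Fitted with the 4 controls alone, without the spread shared with other lines, 21 of the 22 lost their call and kept their direction. Among the remaining targets, yps stood at 16.6% of control, qkr58E-2 at 22.3%, Irp-1A at 24.0%, mub at 30.5%, mod at 31.3%, Rsf1 at 31.5%, hfp at 34.7% and Rbp6 at 36.0%. caz stood at 38.5%, ps at 39.8%, CG1316 at 41.8%, Fmr1 at 43.5%, shep at 44.1%, eIF4H1 at 45.1%, pum at 53.8% and Hrb98DE at 54.3%.

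**Figure D2:**
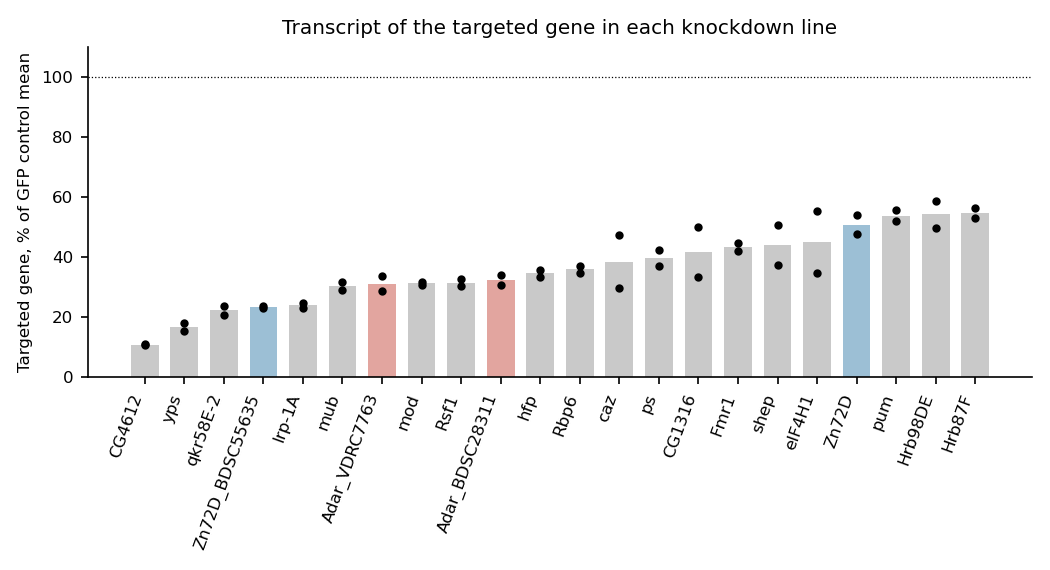
Transcript of the targeted gene in each knockdown line as a percent of the GFP mean, with bars for line means and points for the 2 replicates. Bars run from 10.9% for CG4612 to 54.8% for Hrb87F, and all points lie below the dotted line at the control mean.

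Knockdown of Adar lowered editing at many tested sites. In Adar_VDRC7763, 1898 of 2367 sites were lower and 55 higher, of which 1512 and 42 held with all 3 control sets. In Adar_BDSC28311, 1155 of 2309 sites were lower and 27 higher, of which 794 and 25 held with all 3 control sets. Among the largest falls shared by both lines, a 3' UTR site of rtp (3R 5236332) fell from 93.4 ± 0.88% in GFP to 27.3 ± 1.38% in Adar_BDSC28311 and 8.33 ± 8.42% in Adar_VDRC7763. A coding site of the calcium exchanger gene Nckx30C (2L 9717614) fell from 87.8 ± 1.9% to 36.9 ± 3.04% and 5.14 ± 2.03%, and a coding site of the potassium channel gene Shab (3L 2925255) from 87.3 ± 3.0% to 37.6 ± 2.54% and 6.32 ± 4.22%. A coding site of Rim (3R 17882765), a gene of the presynaptic active zone, fell from 87.0 ± 8.76% to 25.6 ± 2.04% and 8.38 ± 4.78%. A coding site of the sodium leak channel gene na (X 14272092) fell from 96.2 ± 4.8% to 44.3 ± 1.19% and 13.3 ± 6.96%. In the Adar gene itself, the coding site at X 1781840 fell from 35.9 ± 2.42% to 13.9 ± 8.7% and was listed at 0 in Adar_VDRC7763, where the 35 or more reads of each library leave a low level open. The 3' UTR site of Adar at X 1784036 stood at 59.7 ± 4.91% in GFP and 11.3 ± 0.30% in Adar_VDRC7763, and its 45.4 ± 6.55% in Adar_BDSC28311 was not called (adjusted p = 0.126 in the quasi-binomial test). These positions also lie in prage, which overlaps Adar, so the gene they report on is uncertain. The sum of 1182 sites changed in Adar_BDSC28311 was 741 without its replicate 2.

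By gene list, sites in voltage-gated channel genes were lower at 190 and higher at 2 of 321 in Adar_BDSC28311 (195 and 2 adjusted over the list alone), and lower at 261 and higher at 1 of 326 in Adar_VDRC7763 (257 and 1 adjusted over the list alone). Rises were few. In GFP, side-IV (3R 13462029) read 1.67 ± 3.33%, tral 2.36 ± 4.72% (3L 12519598) and 3.68 ± 7.35% (3L 12519462), and cg (2R 14182106) 5.29 ± 7.58%, and in Adar_VDRC7763 they rose to 68.9 ± 5.46%, 64.8 ± 28.7%, 63.9 ± 25.2% and 51.4 ± 6.1%. These calls held without any single library there, and in Adar_BDSC28311 so did those of tral and cg, at 33.3 ± 7.86%, 31.5 ± 0.17% and 42.5 ± 6.73%. The site at 2L 1135014 in CG4577 read 0.317% in controls 1 and 2, 41.8% in controls 3 and 4, 83.0 ± 16.5% in Adar_BDSC28311 and 99.3 ± 0.0217% in Adar_VDRC7763. The rise of the side-IV site to 28.9 ± 26.8% in Adar_BDSC28311 lost its call without Adar_BDSC28311 replicate 1, with 8.64 points then. In GFP 1, 2 and 4 the side-IV site and both tral sites read 0. Positions were not checked against the genotype of the lines, so these rises cannot be told apart from variants between strains.

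The fall was deeper in Adar_VDRC7763. Compared directly, 836 of 1603 sites were higher in Adar_BDSC28311 than in Adar_VDRC7763 and 58 were lower, with a median difference of 5 percentage points, although Adar transcript stood at 32.4% and 31.2% of control. Sites called lower were shared at 1103 of 2158 sites tested in both lines, where independent lists would share 923. Simulated unchanged groups shared 0, but they hold no real changes and leave out the split of the controls. With the controls split between the lines, 991 and 855 were shared. The lines also differed in 1704 genes, a count that was 151 and 1000 without Adar_BDSC28311 replicate 1 or 2 and 195 without Adar_VDRC7763 replicate 1. On the first component Adar_VDRC7763 lay at 81.1 and 47.0, toward GFP 3 and 4, and Adar_BDSC28311 at 5.12 and 17.4, nearer GFP 1 and 2, so this count is not separable from the split of the controls.

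Gene expression also changed in the Adar lines. In Adar_BDSC28311, 695 genes were higher and 1147 lower, but 130 and 218 held with all 3 control sets. In Adar_VDRC7763, 267 were higher and 243 lower, and 156 and 87 held with all 3 control sets. The sum of calls in Adar_BDSC28311 was 2694 without GFP 1, 2667 without GFP 2, 905 without GFP 3, 1077 without GFP 4, and 194 and 593 without its replicate 1 or 2. In Adar_VDRC7763 it was 1003 without GFP 3, 1189 without GFP 4, and 222 and 102 without its replicate 1 or 2. Fitted with the 4 controls alone, 17 genes were called in Adar_BDSC28311 and 0 in Adar_VDRC7763, so the counts rest on the spread shared with other lines, and DESeq2 called 1880 and 671.

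Amy-p (FBgn0000079, 2R 17118636 to 17120303), an amylase gene, rose from 2.88 ± 2.75 CPM to 1124 ± 380 CPM in Adar_BDSC28311 (log2 change 8.72, SE 1.57, edgeR adjusted p = 0.00117) and by 6.89 on the log2 scale (SE 1.51) in Adar_VDRC7763, where the call was lost without replicate 1 (5.37). The protease gene yip7 (FBgn0040060, 3L 6035216 to 6036175) had no count in the controls and was at least 1395-fold higher in Adar_BDSC28311. CG15043 (FBgn0030929) rose by 8.53 (SE 1.78) in Adar_BDSC28311. Jon65Aiii (FBgn0035665), at 166 ± 131 CPM against 0.0603 ± 0.121 CPM, belongs to a family of near-identical genes, so its value is uncertain. Tissue other than brain left on the samples was not tested as a source of the rises of Amy-p, yip7, CG15043 and Jon65Aiii. Members of the neuronal lists fell in Adar_BDSC28311: futsch (FBgn0259108), for a microtubule-associated protein, by log2 change -0.60 (SE 0.10), the syntaxin gene Syx1A (FBgn0013343) by -0.70 (SE 0.13), and the dopamine transporter gene DAT (FBgn0034136) by -0.76 (SE 0.14). The clock gene tim (FBgn0014396, 2L 3493986 to 3508119) was lower in both Adar lines, from 192 ± 15.7 CPM to 69.2 ± 2.43 and 85.3 ± 6.92 CPM. Its call was lost without Adar_BDSC28311 replicate 1 (-1.51), and without Adar_VDRC7763 replicate 1 (-1.26) or 2 (-1.09). The tim transcript was low in mub too, with 1005 expected counts over 2 libraries against 1326 in Adar_BDSC28311. Relative to library size, the clock list gene Pdp1 was lower in Adar_BDSC28311 than in GFP, and cry was higher. The labels give no time of dissection, so a difference in time of day between samples was not excluded for tim. In Adar_VDRC7763, CG7567 (FBgn0039670) rose by 6.78 (SE 1.34), the pigment transporter gene w (FBgn0003996) rose by 1.57 (SE 0.23), and the glial list gene CG6126 (FBgn0038407) fell by 1.09 (SE 0.17). lncRNA:CR40469 (FBgn0058469, X 122493 to 122706) had no count there, against 79.9 ± 70.8 CPM in GFP, whose libraries ranged widely. Genotypes were not used, so a difference in construct or genetic background between Adar_VDRC7763 and GFP was not excluded for w. Of 25 genes named by size in each line, 9 were called with all 3 control sets in Adar_BDSC28311 and 12 in Adar_VDRC7763.

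By list in Adar_BDSC28311, 8 of 10 pan-neuronal genes, 15 of 25 synaptic release genes and 13 of 24 ligand-gated receptor genes were lower, with 1 synaptic release gene higher. Adjusted over the list alone, these were 8, 19 and 13 lower with 1 synaptic release and 1 receptor gene higher, and the tests gave adjusted p = 0.235 with an estimated correlation. Transmitter synthesis and transport had 8 of 16 lower (10 adjusted over the list alone), neuropeptides 9 higher and 1 lower of 33 (10 and 2 adjusted over the list alone), both with adjusted p = 0.316 with an estimated correlation. Of 85 ribosomal protein genes, 70 were higher (78 adjusted over the list alone, adjusted p = 0.235 with an estimated correlation). The last list passed as higher in 21 lines with all 4 controls, and neuropeptides in 19, so these rises were not particular to Adar_BDSC28311. The Adar_BDSC28311 libraries had mean fragment lengths of 204 and 207 bases, below all 4 controls, and 43.4 and 48.5 reads at listed sites per 1000 counted against 51.0 to 64.4 in the controls, so a part of library or RNA quality in these list changes was not excluded.

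Both Zn72D lines had lower editing at a large share of sites, so knockdown of Zn72D went with lower editing in this screen. Whether Zn72D acts on editing directly was not tested. In the Zn72D line 1030 of 2452 sites were lower and 124 higher, of which 698 and 60 held with all 3 control sets. In Zn72D_BDSC55635, 1138 of 2423 were lower and 167 higher, of which 806 and 97 held with all 3 control sets. Of 2322 sites tested in both lines, 863 were lower in both, 80 higher in both and 18 called in opposite directions, 13 of which also differ between the control pairs. Independent lists would share 487 lower and 7.62 higher sites, simulated unchanged groups, with the same limits as above, shared 0, and with the controls split between the lines 693 and 649 lower and 58 and 51 higher sites were shared. The covariance of changes was 189 squared points against 5.01 in the simulations.

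**Figure D3:**
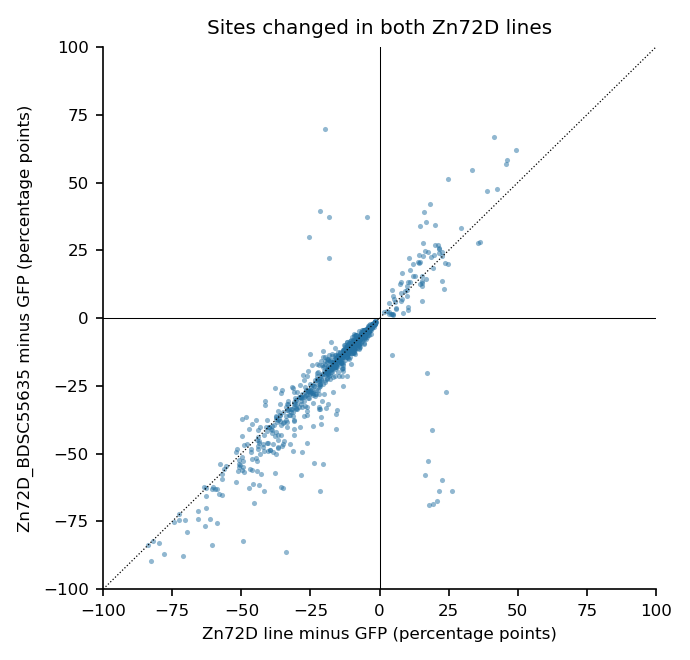
Change in editing level, in percentage points against GFP, in the Zn72D line (x axis) and in Zn72D_BDSC55635 (y axis) for sites called in both lines, with the line of equal change dotted. Of these, 863 fell in both, 80 rose in both and 18 moved in opposite directions.

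The largest shared falls were at coding sites of genes for ion channels and their partners and of Rlip, a gene of Ral signalling. In Rlip, the site at 3R 21018588 stood at 83.8 ± 1.88% in GFP and was listed at 0 in both Zn72D lines, with at least 29 reads in each library, and the site at 3R 21018693 fell from 93.0 ± 5.27% to 10.3 ± 6.19% in the Zn72D line and 3.49 ± 4.93% in Zn72D_BDSC55635. Calcium channel gene Ca-alpha1D (2L 16174153) fell from 89.6 ± 3.51% to 11.6 ± 1.34% and 2.63 ± 2.02%, and Ca-alpha1T (X 6108553) from 86.8 ± 3.81% to 14.2 ± 0.27% and 12.1 ± 0.40%. A site of unc80 (3R 27673289), whose product acts with the sodium leak channel, fell from 83.8 ± 2.37% to 1.83 ± 2.59% and 1.65 ± 2.33%. A site of Shab (3L 2941312) fell from 89.8 ± 3.87% to 18.7 ± 1.79% and 1.85 ± 2.62%, one of qvr (2R 11447623), a potassium channel regulator, from 85.7 ± 3.44% to 16.1 ± 1.04% and 6.8 ± 1.94%, and one of the sodium channel gene para (X 16464719) from 87.1 ± 5.17% to 26.5 ± 4.32% and 3.45 ± 1.49%. All of these kept their call when any single library was left out.

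Some sites rose in both Zn72D lines. An intronic site of Shab (3L 2927350) rose from 7.81 ± 4.1% to 57.0 ± 10.8% and 69.98 ± 3.51%. The 3' UTR of the diacylglycerol kinase gene rdgA had sites at X 9022935, which rose from 13.8 ± 6.53% to 55.0 ± 4.04% and 80.5 ± 0.27%, and at X 9022830, which rose from 8.04 ± 4.17% to 53.7 ± 4.14% and 65.0 ± 4.25%. The 3' UTR of GlyT, a glycine transporter gene (2R 23838782), rose from 14.4 ± 1.6% to 60.7 ± 4.96% and 72.8 ± 6.34%, and that of the acetylcholine receptor gene nAChRbeta1 (3L 4430206) from 19.9 ± 6.73% to 62.3 ± 8.0% and 67.5 ± 3.17%. In the Adar gene, the 3' UTR site at X 1785216 fell from 33.5 ± 8.1% to 0.641 ± 0.91% in the Zn72D line and was listed at 0 in Zn72D_BDSC55635. The coding site at X 1781840 was lower in the Zn72D line (20.2 ± 7.14%), a call lost without Zn72D replicate 1 (-11.2 points), and was not called in Zn72D_BDSC55635 (37.2 ± 1.35%).

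In voltage-gated channel genes, 197 sites were lower and 10 higher of 343 in the Zn72D line (202 and 10 adjusted over the list alone), and 179 lower and 18 higher of 349 in Zn72D_BDSC55635 (179 and 18 adjusted over the list alone). In synaptic release genes, 53 sites were lower and 1 higher of 105, and 59 lower and 5 higher of 117 (53 and 1, and 59 and 6, adjusted over the list alone). Compared with each other, the Zn72D lines differed at 179 of 2129 sites, with 62 higher and 117 lower in Zn72D_BDSC55635. The sum of 1154 sites changed in the Zn72D line was 761 without Zn72D replicate 2. Adar transcript itself was not called changed in either, with log2 changes of -0.17 (SE 0.21) in the Zn72D line and 0.18 (SE 0.21) in Zn72D_BDSC55635.

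Expression of mle (FBgn0002774, 2R 5974857 to 5980778), which encodes a helicase of the dosage compensation complex, fell in both Zn72D lines, from 122 ± 15.1 CPM to 83.6 ± 1.47 CPM (log2 change -0.54, SE 0.08, edgeR adjusted p = 0.000142) and 56.2 ± 1.77 CPM (log2 change -1.11, SE 0.09, edgeR adjusted p = 5.67e-10). It kept its call with all 3 control sets and without any single library. CycJ (FBgn0010317, 3L 3466428 to 3468098), for a cyclin, fell by 2.64 (SE 0.41) and 2.59 (SE 0.38) on the log2 scale, and Gpb5 (FBgn0063368), for a hormone subunit, fell by 1.62 (SE 0.27) and 2.39 (SE 0.28). CG12716 (FBgn0030439) fell by 2.74 (SE 0.47) and 2.75 (SE 0.44), and Tsp42Ek (FBgn0033133) fell by 1.71 (SE 0.25) and 1.36 (SE 0.23). The innexin gene Inx7 (FBgn0027106, X 6991612 to 6993612) rose by 2.31 (SE 0.39) and 2.28 (SE 0.38), CG4020 (FBgn0029821) by 3.95 (SE 0.38) and 2.74 (SE 0.39), and lncRNA:CR45223 (FBgn0266750) by 2.21 (SE 0.16) and 1.60 (SE 0.16). In the Zn72D line, the neuropeptide gene FMRFa (FBgn0000715) rose by 1.01 (SE 0.18) and the calcium channel subunit gene stj (FBgn0261041) by 1.02 (SE 0.18). In Zn72D_BDSC55635, the splicing list gene Pep (FBgn0004401) fell from 170 ± 40.3 CPM to 85.0 ± 2.80 CPM. The direct comparison of the 2 lines covered all 10248 genes, but its values for FMRFa, stj and Pep are not given here.

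The Zn72D line had 490 genes higher and 897 lower, of which 68 and 58 held with all 3 control sets, and Zn72D_BDSC55635 had 441 and 720, of which 108 and 131 held. Of 26 genes named by size or as regulators in each line, 18 and 16 held. The sum of calls in the Zn72D line was 2810 without GFP 1, 2576 without GFP 2, 620 without GFP 3, 587 without GFP 4, and 131 and 102 without its replicate 1 or 2. In Zn72D_BDSC55635 it was 572 without GFP 1, 540 without GFP 2, 2215 without GFP 3, 2194 without GFP 4 and 186 without replicate 2. Fitted with the 4 controls alone, 4 and 0 genes were called. Calls shared by both lines were 40 higher and 55 lower genes, against 21.1 and 63.0 for independent lists and 0 in simulated unchanged groups, and the covariance of log2 changes was -0.0253 against 0.0508 simulated. With the controls split between the lines, 33 and 41 higher and 34 and 50 lower genes were shared. Independent lists would share 2.13 and 575 higher and 3.76 and 528.5 lower genes, so 1 split lay above and the other below, with covariances of 0.0941 and -1.14. The lines themselves differed in 3622 genes, and in 1697 without Zn72D_BDSC55635 replicate 2, 1769 without Zn72D replicate 1 and 1833 without Zn72D replicate 2. They lie on opposite sides of the split of the controls, with Zn72D_BDSC55635 at 83.2 and 91.7 on the first component near GFP 3 and 4 and the Zn72D line at -14.3 and -11.4 near GFP 1 and 2, so this count is not separable from that split. Among lists in the Zn72D line, 20 of 71 oxidative phosphorylation genes, 13 of 19 muscle genes and 14 of 24 glial genes were lower, with 1 glial gene higher (35, 15 and 17 lower and 2, 0 and 2 higher adjusted over the list alone). The tests gave adjusted p = 0.368 with an estimated correlation, and none of these lists passed as lower in Zn72D_BDSC55635. In Zn72D_BDSC55635, 65 of 85 ribosomal protein genes were lower and 1 higher (73 and 1 adjusted over the list alone, adjusted p = 0.612 with an estimated correlation).

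Across the screen, the mean editing level asked which other proteins alter editing as a whole. It was 14.65 ± 0.50% in GFP over 2345 sites, 3.42 ± 0.10% in Adar_VDRC7763, 7.53 ± 0.24% in Adar_BDSC28311, 8.81 ± 0.11% in Zn72D_BDSC55635 and 9.29 ± 0.11% in the Zn72D line. Among the other 18 lines it ranged from 12.72% for ps to 14.95% for yps, and both replicates lay below all 4 controls in 3 of them, namely ps (12.72 ± 0.20%), Rbp6 (12.96 ± 0.14%) and eIF4H1 (13.78 ± 0.23%). With reads pooled over sites, the difference from GFP in percentage points was -0.711 in ps (-1.92 in the main measure), -1.33 in Rbp6 (-1.69) and 0.178 in eIF4H1 (-0.866), and 13 of the 18 lines went from below to above GFP. No line can pass 0.05 in this test: exact two-sided permutation p was 0.0667 in the Adar, Zn72D, ps and Rbp6 lines, the smallest that 15 splits allow, and 0.245 after Benjamini-Hochberg adjustment over 22 lines.

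**Figure D4:**
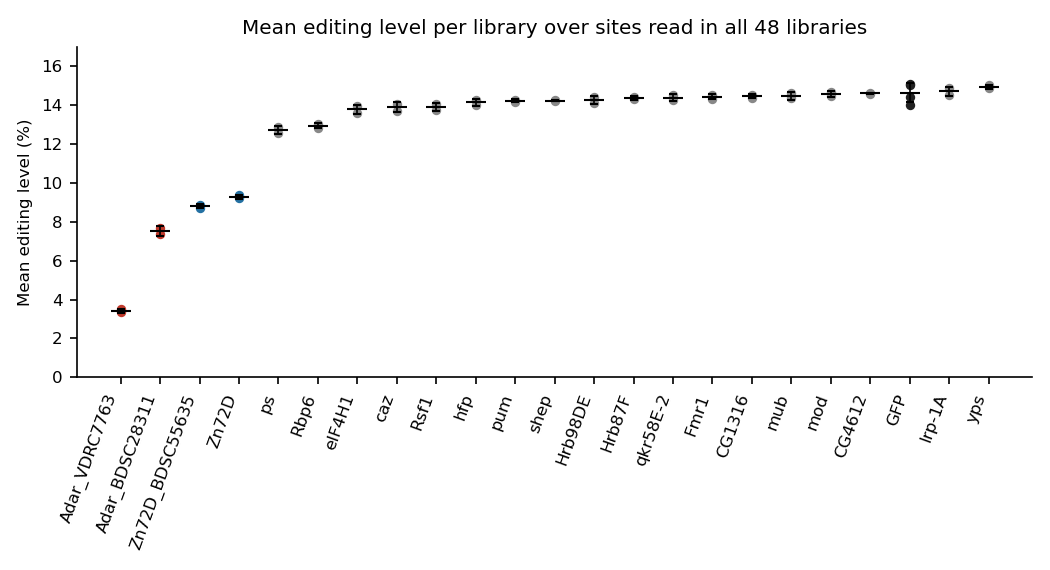
Mean editing level in percent over 2345 sites for each library (points), with group means and SD as black bars, ordered by mean. The Adar and Zn72D lines lie between 3.42% and 9.29%, ps and Rbp6 at 12.72% and 12.96%, and the GFP mean at 14.65%.

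Adar transcript was called lower in the Fmr1 line (log2 change -0.74, SE 0.21, edgeR adjusted p = 0.0283), the pum line (-0.77, SE 0.21, edgeR adjusted p = 0.0245) and the ps line (-0.63, SE 0.21, edgeR adjusted p = 0.036), but not in these with controls 1 and 2 alone. Over groups that do not target Adar, the Zn72D lines form a cluster of their own in mean editing, so the relation is given here without them. Across the 19 groups left, Pearson's r of Adar CPM and mean editing was 0.305 (permutation p = 0.207) and Spearman's rho was 0.274 (permutation p = 0.255). Without CG4612 and hfp, the groups farthest from the median Adar level, r was 0.291 (permutation p = 0.258). No relation was shown at this number of groups.

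Knockdown of ps, the pasilla gene, whose product is an RNA-binding splicing factor, changed editing most among the other 18 lines, with 233 of 2501 sites lower and 55 higher, of which 112 and 15 held with all 3 control sets. Coding sites of OtopLa, a gene of the otopetrin channel family, fell from 70.9 ± 3.94% to 12.9 ± 0.27% (X 5630114) and from 75.6 ± 1.91% to 18.7 ± 2.67% (X 5631048). A coding site of nAChRalpha5 (2L 14083460) rose from 6.99 ± 4.01% to 34.3 ± 0.60%. In voltage-gated channel genes, 65 sites were lower and 5 higher of 356 (87 and 6 adjusted over the list alone), and of 1031 coding exon sites 141 were lower. The sum of 288 sites changed fell to 142 without ps replicate 1 and 101 without replicate 2. Knockdown of Rbp6 lowered 74 of 2430 sites and raised 5, of which 37 and 1 held with all 3 control sets, and lowered 25 of 346 sites in voltage-gated channel genes (38 adjusted over the list alone). Its sum of 79 was 124 without GFP 1, 128 without GFP 2, 50 without GFP 4, and 14 and 23 without Rbp6 replicate 1 or 2.

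**Figure D5:**
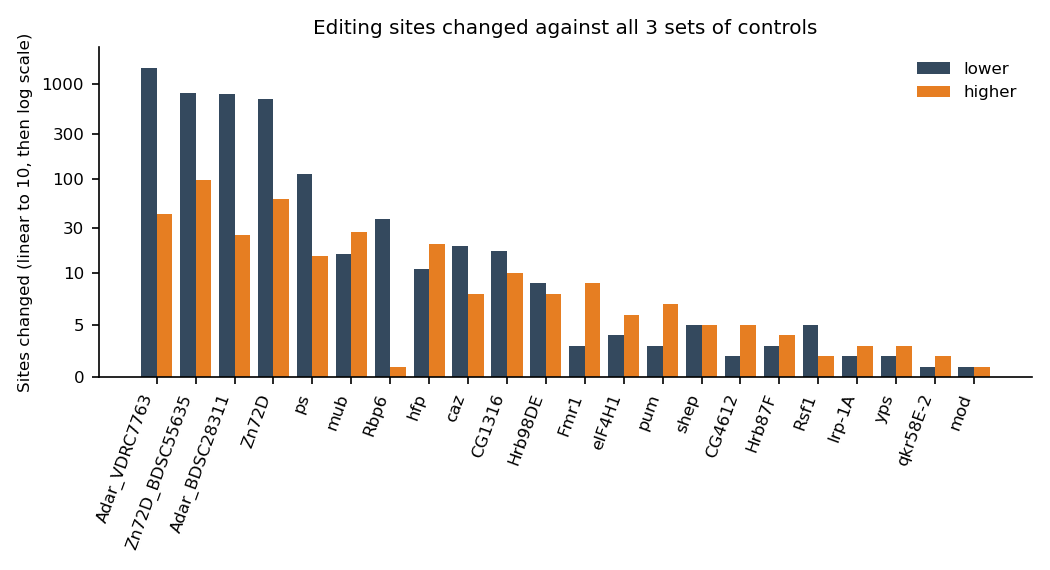
Sites lower (dark) and higher (orange) than GFP with all 3 control sets in each line, on an axis that is linear to 10 and logarithmic above. Counts of lower sites run from 1512 in Adar_VDRC7763 and 112 in ps to 1 in mod and qkr58E-2.

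In the remaining lines, sites lower and higher with all 3 control sets numbered 16 and 27 in mub, 11 and 20 in hfp, 19 and 8 in caz, 17 and 10 in CG1316, and 9 and 8 in Hrb98DE. Sums in the remaining 11 lines ran from 2 in mod to 12 in Fmr1. CG1316 knockdown lowered an intronic site of CaMKII (4 1041307), a kinase gene, from 69.0 ± 4.52% to 17.1 ± 1.78%, and a coding site of the calcium channel gene cac (X 11954277) from 76.8 ± 4.32% to 29.8 ± 8.65%, and both calls held without any single library. CG1316 replicate 2 was unlike all other libraries, with 15.2% of counts in its 3 most abundant genes (4.07 to 8.06% elsewhere) and a mean fragment length of 174 bases (204 to 263 elsewhere). The sum of 1999 genes changed in CG1316 was 5 without it and 2109 without replicate 1. Over the 18 lines, the cpx coding site at 3R 4297504, in the gene for complexin, was lower in 11 lines with all 3 control sets, from 61.1% in GFP, and the para site at X 16505550 was lower in 5. An IA-2 site in the 3' UTR (2L 1010857), at 15.9% in GFP and 1.02% in Adar_VDRC7763, was higher in 16 of the 18 lines. All 18 comparisons share the same 4 controls, so such counts over lines can also arise from the level of the controls. The sum of 88 sites changed in mub was 37 and 29 without mub replicate 1 or 2, and that of 72 in hfp was 135 without GFP 1 and 26 and 25 without hfp replicate 1 or 2. The sum of 103 in caz was 42 without GFP 4 and 34 and 33 without caz replicate 1 or 2, and that of 88 in CG1316 was 57 without GFP 4 and 53 and 23 without CG1316 replicate 1 or 2. The sum of 30 in Hrb98DE was 71 without GFP 1, 48 without GFP 2, and 15 and 7 without Hrb98DE replicate 1 or 2.

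At some sites changed in these lines, levels lay at the ends or the middle of the scale. A 3' UTR site of dysc (3L 13869566), at 0.602 ± 0.78% in GFP, read 53.2 ± 7.31% in caz, 55.6 ± 0.29% in hfp and 65.0 ± 1.2% in mub. The sotv site at 2R 16147662 read 47.9 ± 9.28% in GFP and was listed at 0 in Fmr1 and hfp, and the metro site at 2R 11229833 read 33.4 ± 23.7% in GFP and 100% in CG4612 and Hrb87F. Positions were not checked against the genotype of the lines.

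Gene expression in the other 18 lines was compared for the same question, which genes respond to loss of each RNA-binding protein. Genes called with all 3 control sets numbered 195 higher and 154 lower in Hrb98DE, 184 and 92 in eIF4H1, 97 and 141 in ps, 104 and 114 in mub and 84 and 65 in hfp. They numbered 34 and 17 in caz, 25 and 27 in shep, 24 and 22 in CG1316, 12 and 25 in Rsf1 and 16 and 17 in Rbp6. In Irp-1A they were 7 and 12, in yps 8 and 8, in CG4612 10 and 4, in Fmr1 8 and 3, in qkr58E-2 3 and 8, in Hrb87F 3 and 7, in pum 4 and 6, and in mod 1 and 1. With all 4 controls together, sums ran from 627 in Hrb87F to 2064 in ps. Over all 22 lines these sums moved to a median of 224% of their value without GFP 1, 205% without GFP 2, 28.0% without GFP 3, 25.9% without GFP 4 and 5.46% without 1 replicate of the line, so the counts depend on each control and on both replicates of a line.

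In hfp, the Arc1 gene (FBgn0033926, 2R 14357927 to 14360297), for a capsid-like protein of neurons, rose from 370 ± 45.6 CPM to 4957 ± 35.4 CPM (log2 change 3.75, SE 0.17, edgeR adjusted p = 3.77e-15). The channel genes Elk (FBgn0011589) and Ca-alpha1T (FBgn0264386) rose by 1.09 (SE 0.11) and 1.39 (SE 0.21), and stnB (FBgn0016975) fell by 0.69 (SE 0.11). As a list, 11 of 24 voltage-gated channel genes were higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.573 with an estimated correlation), while 18 of these 24 genes were lower in controls 3 and 4 than in 1 and 2. The change in hfp was not limited to channels. There 48 of 85 ribosomal protein and 7 of 33 neuropeptide genes were higher, and 5 of 16 transmitter genes were lower. Camera with an estimated correlation gave these lists adjusted p = 0.573 too. The rises were not particular to hfp: with all 4 controls, ribosomal proteins passed as higher in 21 lines and neuropeptides in 19. Between the control pairs, 68 of the 85 ribosomal protein genes were lower in controls 3 and 4.

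In mub, the opsin gene Rh5 (FBgn0014019, 2L 12008153 to 12009832) fell from 151 ± 32.5 CPM to 2.06 ± 0.30 CPM (log2 change -6.18, SE 0.46, edgeR adjusted p = 7.36e-10). The peptide genes Crz (FBgn0013767) and AstA (FBgn0015591) rose by 1.54 (SE 0.20) and 0.83 (SE 0.11), the glutamate receptor gene Nmdar2 (FBgn0053513) rose by 1.00 (SE 0.13), and ort (FBgn0003011), for a histamine receptor, fell by 0.96 (SE 0.18). In ps, vision genes fell: ort by 1.66 (SE 0.19), inaF-B (FBgn0259918) with a log2 change of -2.01 (SE 0.29) and Gbeta76C (FBgn0004623) with -2.22 (SE 0.36). Eye tissue left on the brains was not measured, so dissection was not excluded for these genes in ps or for Rh5 in mub. Of 24 photoreceptor genes, 13 were lower in ps (17 adjusted over the list alone, adjusted p = 0.547 with an estimated correlation). Other lists moved there too: 13 of 24 glial genes, 23 of 71 oxidative phosphorylation genes, 10 of 25 release genes and 4 of 16 transmitter genes were lower, with 1 oxidative phosphorylation and 2 release genes higher, and 65 of 85 ribosomal protein and 8 of 33 neuropeptide genes were higher. Adjusted over the list alone these were 14, 26, 16 and 8 lower with 1 oxidative phosphorylation, 2 release and 1 transmitter gene higher, and 72 and 8 higher with 1 neuropeptide gene lower, with adjusted p of 0.547 or 0.593 with an estimated correlation. Several of these lists were not particular to ps. With all 4 controls, glia passed as lower in 20 lines, ribosomal proteins as higher in 21 and neuropeptides as higher in 19. The dopa decarboxylase gene Ddc (FBgn0000422) fell by 1.12 (SE 0.16) in ps, and the active zone gene brp (FBgn0259246) rose by 0.66 (SE 0.11). Another screened gene, yps (FBgn0022959), rose in ps by 1.02 (SE 0.12) and in mub by 0.89 (SE 0.12).

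In shep, genes of transmitter use fell: Gad1 (FBgn0004516), for glutamate decarboxylase, by 1.34 (SE 0.23), Vmat (FBgn0260964) by 0.93 (SE 0.12) and DAT by 0.95 (SE 0.15). The release genes Rop (FBgn0004574) and comt (FBgn0000346) fell by 1.17 (SE 0.18) and 1.06 (SE 0.16), and the peptide gene AstA fell by 0.99 (SE 0.13). Gad1, Rop and comt differed by control pair, with -0.69, -0.73 and -0.66 against controls 1 and 2 and -1.78, -1.51 and -1.37 against controls 3 and 4. As lists, 10 of 16 transmitter genes (12 lower and 1 higher adjusted over the list alone, adjusted p = 0.191 with an estimated correlation) and 14 of 25 release genes were lower, with 1 release gene higher (18 and 2 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation). The fall was not limited to these lists: 13 of 24 glial genes (15 adjusted over the list alone, adjusted p = 0.253 with an estimated correlation) and 13 of 19 muscle genes (14, adjusted p = 0.375) were lower too, and 51 of 85 ribosomal protein genes were higher (72, adjusted p = 0.253). These changes were not particular to shep. With all 4 controls, glia passed as lower in 20 lines, muscle as lower in 16 and ribosomal proteins as higher in 21. Synaptic release passed as lower in 12 lines and transmitter synthesis in 7. Hsp68 (FBgn0001230) rose by 2.98 (SE 0.43) in shep, but by 0.22 without shep replicate 1, where the call was lost.

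In eIF4H1, the insulin-like peptide gene Ilp3 (FBgn0044050, 3L 9801298 to 9802120) fell from 44.7 ± 10.4 CPM to 9.1 ± 1.77 CPM (log2 change -2.29, SE 0.25, edgeR adjusted p = 3.99e-07). CG11342 (FBgn0035537) rose by 3.37 (SE 0.33), the splicing list genes Pep and Rm62 (FBgn0003261) rose by 1.05 (SE 0.14) and 0.80 (SE 0.12), and loqs (FBgn0032515), a small RNA pathway gene, rose by 0.61 (SE 0.11). Glial Gs2 (FBgn0001145) fell by 0.98 (SE 0.17). In Hrb98DE, Crz rose by 1.39 (SE 0.20), AstC (FBgn0032336) by 0.82 (SE 0.12), NPF (FBgn0027109) by 0.80 (SE 0.17), and Thor (FBgn0261560), for a translation repressor, from 39.6 ± 11.4 CPM to 113 ± 12.5 CPM. The antimicrobial peptide gene Mtk (FBgn0014865) rose by 5.64 (SE 0.89), but read -1.74 without Hrb98DE replicate 2, and 18 of 20 immune genes were higher (18 adjusted over the list alone, adjusted p = 0.470 with an estimated correlation), a list not tested without that replicate. Other lists moved in Hrb98DE too, with 16 of 24 glial and 5 of 16 transmitter genes lower. In the same line 72 of 85 ribosomal protein and 12 of 33 neuropeptide genes were higher. Camera with an estimated correlation gave these lists adjusted p of 0.411 or 0.470. They were not particular to Hrb98DE: with all 4 controls, glia passed as lower in 20 lines and transmitter synthesis in 7. Ribosomal proteins passed as higher in 21 lines and neuropeptides in 19. In CG4612, AstC rose by 1.09 (SE 0.12), and 15 of 33 neuropeptide genes were higher and 1 lower (18 and 2 adjusted over the list alone, adjusted p = 0.0261 with an estimated correlation). Of these 15 genes 3 were called with all 3 control sets, and of the 33 genes 4 were higher and 11 lower in controls 3 and 4 than in controls 1 and 2. In CG4612 14 of 24 glial genes and 23 of 71 oxidative phosphorylation genes were lower, with 1 of the latter higher, and 16 of 85 ribosomal protein genes were higher (17 and 32 lower with 2 of the latter higher, and 55 higher, adjusted over the list alone, adjusted p = 0.394 with an estimated correlation). In caz, CG17005 (FBgn0032109) rose by 5.59 (SE 0.58). In Rsf1, the innexin gene Inx2 (FBgn0027108) fell by 0.93 (SE 0.13).

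Over the 22 lines and 23 lists, 202 of 506 list tests passed with the preset correlation, 72 of them with all 3 control sets, 103 by fry, and 1, neuropeptides in CG4612, with an estimated correlation. With all 3 control sets, neuropeptides were higher in 17 lines, ribosomal proteins higher in 16 and lower in 1, glia lower in 15, transmitter synthesis lower in 6 and synaptic release lower in 4. Muscle and oxidative phosphorylation were each lower in 3 lines, trachea lower in 2 (Irp-1A and yps), and photoreceptor (ps), pan-neuronal and ligand-gated receptor lists (Adar_BDSC28311) lower in 1. Immune genes (Hrb98DE) and voltage-gated channels (hfp) were higher in 1 line. The 22 results share the controls and are not independent. Every list named so far in this paragraph as passing with all 3 control sets includes members that differ between the control pairs. Screened RNA-binding proteins, circadian clock, heat shock, stress and apoptosis, hemocyte, dosage compensation, background markers and splicing factors passed in some lines with all 4 controls but in 0 with all 3 control sets. Fat body and antiviral RNAi passed in 0 lines.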

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

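Of the tests of explanations in this part, those of transcript length and of the ratio of read depth were written before the result was seen, and all other tests were chosen only after it was seen. Chance alone flags about 1 in 20 groups in a search for libraries far from the others, and 9 of 99 control values tested had such a library.

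The first pattern weighed is the difference between controls 3 and 4 and controls 1 and 2, with 4809 genes and 58 sites. More fat body left on the brains does not match it, since at least 6 fat body genes were called in each direction, nor does a trend with transcript length (squared Spearman correlation 0.0348). Younger adults in controls 3 and 4 may contribute, as 94.1% of called cuticle genes were higher there, but muscle and tracheal genes were higher too and age could not be told apart from dissection. Strain variants between the pairs of controls might explain part of the sites: the median ratio of the Adar_BDSC28311 level to that over libraries not targeting Adar was 0.789 (0.383 over all tested sites), which decides nothing, and a further test added after that value found 11 of 13 sites under 2% in controls 1 and 2 at 20% or more in both Adar lines. Of the 58 sites, 34 lay on chromosome 3R, or 58.6% against 22.5% of the tested sites. Of the 13 sites, 12 were at 20% or more in Zn72D_BDSC55635 and 0 in the Zn72D line. In all 18 lines other than Adar and Zn72D, 9 of the 13 stayed under 2%. Genotypes were not used, so variants were not shown directly. No biological cause other than age was tested.

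The second pattern is the sites that changed in the 18 lines other than Adar and Zn72D, 68 of them higher and 169 lower with all 3 control sets. Low read depth stays open for part of the higher sites: their lowest control reads had a median 1.39 times that of all tested sites, which decides nothing because deeper sites are called more easily, but all 41 that could be tested with at least 50 reads in every library stayed called. Strain variants at listed positions may account for some of them: 69.1% of the higher and 93.5% of the lower sites depend on Adar, against 89.8% of all tested, but sites near 0 in the controls can hardly meet this measure, and of the 51 higher sites at 2% or more 82.4% do. Of the 17 under 2% in the controls, 7 were at 20% or more in an Adar line. All 18 lines share the same controls, so sites higher in many lines could reflect the level of the controls, and no biological explanation was tested.

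The third pattern is the fall in editing in both Zn72D lines. Less Adar transcript alone does not explain it. The 13 other lines with less Adar transcript than both Zn72D lines had a mean editing level of at least 12.7%. The lower of the 2 log2 changes of Adar, -0.17 with SE 0.21, leaves a modest fall open and decides nothing by itself. Adar stood at 450 and 436 CPM in the Zn72D line, against 433 and 429 in GFP 1 and 2 and 596 and 538 in GFP 3 and 4. Strain variants at listed positions do not explain most of it, since 97.6% of the sites lower in both lines depend on Adar, against 92.1% of all sites tested in both. A change in Adar protein or in its action on these transcripts may remain, at 12.7% against 9.29% and 8.81%, and was not tested because protein was not measured.

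Single control libraries were flagged by their gap to the nearest other control over the range of all 4. This ratio is 1 whenever the other controls are equal, as at 0 or 100%, so it does not give the size of a difference. GFP 3 was flagged at rtp 3R 5236332 (92.1%, others 93.75 to 93.94%). With the other controls at 0, it was also flagged at side-IV 3R 13462029 (6.67%), tral 3L 12519598 (9.45%), tral 3L 12519462 (14.7%) and Msp300 2L 5123366 (3.45%). GFP 4 was flagged at Shab 3L 2927350 (14.0%, others 5.455 to 6.061%) and Treh 2R 21086617 (99.4%, others 100%). GFP 2 was flagged at unc80 3R 27673289 (87.3%, others 82.24 to 82.95%), and GFP 1 at Pitslre 3L 20773150 (67.1%, others 61.33 to 61.9%).

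The Adar lines differed from each other in 1704 genes and 894 sites, and the gene count is not separable from the split of the controls (first component 81.1 and 47.0 in Adar_VDRC7763 against 5.12 and 17.4 in Adar_BDSC28311). As Adar_BDSC28311 minus Adar_VDRC7763, log2 differences were 7.39 for CG11313, with 1 expected count in Adar_VDRC7763, and -5.86 for hll. The fitted 10.25 for lncRNA:CR40469 gives no size, since that gene had no count in Adar_VDRC7763. Differences in percentage points, taken between pooled reads and so not equal to those between mean levels, were 19.0 at rtp 3R 5236332, 26.5 at CG42540 3L 4585859, 22.1 at nAChRbeta1 3L 4430208 and 31.4 at na X 14272092. They were 31.8 at Nckx30C 2L 9717614, 9.38 at rdgA X 9027170, 31.1 at Shab 3L 2925255 and 35.3 at CG1090 3R 4365385. Lower in Adar_BDSC28311 were CG4577 2L 1135014 (-15.7), side-IV 3R 13462029 (-36.9), tral 3L 12519598 (-32.9) and tral 3L 12519462 (-33.3). At these positions, which rose in the Adar lines, variants between strains were not excluded. Sites in Adar differed by 14.9 at X 1781840, 33.4 at X 1784036, 5.26 at X 1785212 and 9.44 at X 1785216.

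The Zn72D lines differed from each other in 3622 genes and 179 sites, and they lie on opposite sides of the split of the controls on the first component (83.2 and 91.7 against -14.3 and -11.4). As Zn72D_BDSC55635 minus Zn72D, log2 differences were -1.12 for Zn72D itself, -0.57 for mle, 2.78 for TwdlG, -1.21 for CG4020 and -0.62 for lncRNA:CR45223. They were -1.07 for lncRNA:CR43837, -1.41 for asRNA:CR45479, an antisense gene whose value is uncertain, and -3.53 for CG9451. CG11313 stood at -7.35, a value near the floor, with 1 expected count in Zn72D_BDSC55635, as in Adar_VDRC7763. Differences in percentage points, again of pooled reads, were -9.14 at Ca-alpha1D 2L 16174153, -17.0 at Shab 3L 2941312, -9.24 at qvr 2R 11447623 and -23.0 at para X 16464719. They were 25.4 at rdgA X 9022935 and 16.9 at Adar X 1781840.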

How the results depend on the processing

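Direction held for most results, while counts depended on the controls. Gene counts with RLE normalization, DESeq2 and no filter on low counts stayed within 1.5 times of the main count in 22 of 22 lines. The side of the threshold, and for called values the direction, were kept by 2590 of 2948 values for named genes, 2081 of 2294 for named sites and 265 of 286 for targeted genes. The named genes counted here were those called with all 3 control sets. Their 227 values with each pair of controls were therefore fixed by that choice and show nothing about robustness. With the line and controls alone in the fit, 10 values for named genes kept the call and 214 lost it. Where counts moved the cause was not tested, except that smaller sets of controls, sites or libraries hold less information by construction. Depth limits the sites: of 13091 listed, 2345 were read at least 20 times in every library. When 1 of 2 replicates of a line is left out, the lone sample is assumed to vary like the other groups.

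With controls 1 and 2 only, the count of changed genes was 964 in Adar_BDSC28311, 3714 in Adar_VDRC7763, 83 in caz, 74 in CG1316, 24 in CG4612, 403 in eIF4H1, 16 in Fmr1 and 383 in hfp. Further values were 13 in Hrb87F, 762 in Hrb98DE, 41 in Irp-1A, 4 in mod, 470 in mub, 369 in ps, 21 in pum and 20 in qkr58E-2. Then came 51 in Rbp6, 61 in Rsf1, 70 in shep, 21 in yps, 216 in Zn72D and 4729 in Zn72D_BDSC55635. With controls 3 and 4 only, the count of changed genes was 4716 in Adar_BDSC28311, 1229 in Adar_VDRC7763, 4865 in caz, 5195 in CG1316, 4691 in CG4612, 4987 in eIF4H1, 5028 in Fmr1 and 4361 in hfp. Further values were 4637 in Hrb87F, 4566 in Hrb98DE, 4398 in Irp-1A, 4811 in mod, 4754 in mub, 5241 in ps, 4961 in pum and 4836 in qkr58E-2. Then came 4634 in Rbp6, 4870 in Rsf1, 4842 in shep, 5009 in yps, 4783 in Zn72D and 549 in Zn72D_BDSC55635.

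With the line and controls alone in the fit, the count of changed genes was 17 in Adar_BDSC28311, 0 in Adar_VDRC7763, 1 in caz, 0 in CG1316, 0 in CG4612, 1 in eIF4H1, 0 in Fmr1 and 1 in hfp. Further values were 0 in Hrb87F, 0 in Hrb98DE, 0 in Irp-1A, 0 in mod, 1 in mub, 3 in ps, 0 in pum and 1 in qkr58E-2. Then came 0 in Rbp6, 0 in Rsf1, 0 in shep, 0 in yps, 4 in Zn72D and 0 in Zn72D_BDSC55635. With all 3 control sets, a stricter count by construction, it was 348 in Adar_BDSC28311, 243 in Adar_VDRC7763, 51 in caz, 46 in CG1316, 14 in CG4612, 276 in eIF4H1, 11 in Fmr1 and 149 in hfp. Further values were 10 in Hrb87F, 349 in Hrb98DE, 19 in Irp-1A, 2 in mod, 218 in mub, 238 in ps, 10 in pum and 11 in qkr58E-2. Then came 33 in Rbp6, 37 in Rsf1, 52 in shep, 16 in yps, 126 in Zn72D and 239 in Zn72D_BDSC55635.

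Replicate numbers were checked as a pairing: over 231 pairs of groups the median correlation of the replicate difference was 0.0156 (range -0.367 to 0.405), and 23.8% of pairs were over 0.1, so numbers do not pair samples. The replicate block leaves controls 3 and 4 with no partner by construction. With the replicate block, changed genes numbered 1003 in Adar_BDSC28311, 3736 in Adar_VDRC7763, 86 in caz, 80 in CG1316, 27 in CG4612, 398 in eIF4H1, 21 in Fmr1 and 397 in hfp. Further values were 15 in Hrb87F, 814 in Hrb98DE, 32 in Irp-1A, 6 in mod, 505 in mub, 378 in ps, 22 in pum and 23 in qkr58E-2. Then came 55 in Rbp6, 63 in Rsf1, 69 in shep, 21 in yps, 217 in Zn72D and 4757 in Zn72D_BDSC55635. Changed sites with the replicate block numbered 27 in caz, 19 in CG1316, 11 in eIF4H1, 8 in Fmr1, 35 in hfp, 5 in Hrb87F, 19 in Hrb98DE and 4 in Irp-1A. Further values were 3 in mod, 39 in mub, 172 in ps, 43 in Rbp6, 7 in Rsf1, 9 in shep and 5 in yps.

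Leaving out each library in turn gave changed genes from 194 to 2694 in Adar_BDSC28311, 102 to 1189 in Adar_VDRC7763, 49 to 2699 in caz, 5 to 3453 in CG1316, 3 to 2771 in CG4612 and 274 to 3043 in eIF4H1. Further values were 10 to 2915 in Fmr1, 92 to 2236 in hfp, 5 to 2313 in Hrb87F, 224 to 2761 in Hrb98DE, 15 to 1964 in Irp-1A and 3 to 2743 in mod. Then came 193 to 2883 in mub, 221 to 3438 in ps, 2 to 3092 in pum, 3 to 2776 in qkr58E-2, 20 to 2293 in Rbp6 and 17 to 2859 in Rsf1. The last were 34 to 2786 in shep, 6 to 2977 in yps, 102 to 2810 in Zn72D and 186 to 2215 in Zn72D_BDSC55635. For changed sites the same gave 741 to 1240 in Adar_BDSC28311, 33 to 136 in caz, 23 to 121 in CG1316, 3 to 46 in CG4612, 7 to 90 in eIF4H1, 13 to 94 in Fmr1 and 25 to 135 in hfp. Further values were 6 to 73 in Hrb87F, 7 to 71 in Hrb98DE, 2 to 56 in Irp-1A, 3 to 21 in mod, 29 to 132 in mub, 101 to 309 in ps and 9 to 49 in pum. Then came 1 to 30 in qkr58E-2, 14 to 128 in Rbp6, 4 to 67 in Rsf1, 6 to 54 in shep, 5 to 70 in yps and 761 to 1200 in Zn72D. Genes that differ between the Adar lines ranged from 151 to 1449, and those between the Zn72D lines from 1697 to 2686. Mtk in Hrb98DE reversed to a log2 change of -1.74 without Hrb98DE replicate 2, and was 6.62 without replicate 1.

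With controls 1 and 2 only, changed sites numbered 60 in caz, 41 in CG1316, 17 in CG4612, 28 in Fmr1 and 13 in Hrb87F. Further values were 16 in Irp-1A, 26 in pum, 13 in qkr58E-2 and 15 in yps. With controls 3 and 4 only they numbered 234 in caz, 183 in CG1316, 108 in CG4612, 169 in eIF4H1, 175 in Fmr1 and 179 in hfp. Further values were 139 in Hrb87F, 111 in Hrb98DE, 128 in Irp-1A, 87 in mod, 199 in mub and 115 in pum. Then came 95 in qkr58E-2, 163 in Rbp6, 132 in Rsf1, 139 in shep and 158 in yps. With all 3 control sets they numbered 27 in caz, 27 in CG1316, 7 in CG4612, 10 in eIF4H1, 12 in Fmr1 and 31 in hfp. Further values were 7 in Hrb87F, 17 in Hrb98DE, 5 in Irp-1A, 2 in mod, 43 in mub and 127 in ps. Then came 3 in qkr58E-2, 38 in Rbp6, 7 in Rsf1, 10 in shep, 5 in yps and 758 in Zn72D. With a dispersion from the line and controls alone they numbered 22 in caz, 20 in CG1316, 3 in CG4612, 6 in eIF4H1, 10 in Fmr1 and 16 in hfp. Further values were 4 in Hrb87F, 5 in Hrb98DE, 2 in Irp-1A, 2 in mod, 37 in mub and 128 in ps. Then came 8 in pum, 2 in qkr58E-2, 13 in Rbp6, 3 in Rsf1, 7 in shep and 4 in yps.

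A coverage minimum of 10, which tests more sites, gave changed sites of 18 in CG4612, 56 in eIF4H1, 76 in Fmr1, 31 in Hrb87F and 23 in Irp-1A. Further values were 11 in mod, 24 in pum, 40 in Rsf1, 30 in shep and 47 in yps. A coverage minimum of 50, which tests fewer sites, gave 628 in Adar_BDSC28311, 977 in Adar_VDRC7763, 63 in caz, 5 in CG4612, 11 in Fmr1, 44 in hfp and 10 in Hrb87F. Further values were 8 in pum, 2 in qkr58E-2, 12 in Rsf1, 10 in shep, 642 in Zn72D and 745 in Zn72D_BDSC55635. It gave 488 sites that differ between the Adar lines and 100 between the Zn72D lines. With no minimum editing level there were 19 in CG4612, 70 in eIF4H1, 39 in Hrb87F, 21 in Irp-1A, 43 in Rsf1, 30 in shep and 42 in yps. The Fisher exact test on pooled reads, which leaves out spread between replicates, gave 188 in caz, 163 in CG1316, 83 in CG4612, 128 in eIF4H1, 122 in Fmr1 and 205 in hfp. Further values were 97 in Hrb87F, 100 in Hrb98DE, 97 in Irp-1A, 57 in mod, 158 in mub and 91 in pum. Then came 68 in qkr58E-2, 182 in Rbp6, 110 in Rsf1, 90 in shep and 95 in yps. Counting only sites that depend on Adar left 23 in Fmr1, 11 in Hrb87F, 5 in pum and 9 in shep.

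With reads pooled over sites, the difference in mean editing in percentage points was -5.84 in Adar_BDSC28311, -9.85 in Adar_VDRC7763, 0.129 in caz, 0.863 in CG1316, 0.178 in eIF4H1, 0.850 in Fmr1, 0.425 in hfp and 0.897 in mod. Further values were 0.361 in mub, -0.711 in ps, 0.612 in pum, 0.639 in qkr58E-2, -0.0120 in Rsf1, 0.236 in shep, 1.18 in yps and -4.32 in Zn72D. In the lines left, where it moved by less than the control SD, the difference was 0.459 in CG4612, 0.220 in Hrb87F and 0.0732 in Hrb98DE. It was 0.427 in Irp-1A, -1.33 in Rbp6 and -5.98 in Zn72D_BDSC55635. A coverage minimum of 50 gave -6.40 in Adar_BDSC28311 and -10.5 in Adar_VDRC7763. With the line and controls alone in the fit, the targeted gene lost its call with a log2 change of -1.61 in Adar_BDSC28311, -1.69 in Adar_VDRC7763, -1.36 in caz, -1.25 in CG1316, -3.20 in CG4612, -1.14 in eIF4H1 and -1.17 in Fmr1. Further values were -1.53 in hfp, -0.86 in Hrb87F, -0.86 in Hrb98DE, -2.06 in Irp-1A, -1.67 in mod, -1.70 in mub and -1.32 in ps. Then came -0.88 in pum, -1.48 in Rbp6, -1.66 in Rsf1, -1.17 in shep, -2.59 in yps, -0.98 in Zn72D and -2.10 in Zn72D_BDSC55635.

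List tests past the threshold fell from 202 to 1 with an estimated correlation, 103 with fry and 101 with controls 1 and 2 only. The Pearson r of Adar transcript level and mean editing, -0.232 over all 21 groups, was 0.0320 with deposited TPM, 0.305 without the Zn72D lines, and 0.280 with controls 1 and 2 only and without the Zn72D lines. The Zn72D lines account for the change of sign by construction in the last 2 settings, and the cause was not tested for TPM.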

Other observations

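Some listed positions differed between lines. The bru3 position at 3L 13535416, at 54.9% in GFP and 54.3% in Adar_VDRC7763, was higher in 7 of the 18 other lines and reached 100% in single libraries. The Nckx30C position at 2L 9725854 was listed at 0 in GFP and was higher in 6 lines, and the Treh position at 2R 21086617, at 99.85% in GFP and 100% in Adar_VDRC7763, was lower in 6.

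Among positions lower in several of the 18 other lines, cpx 3R 4297518 (42.2% in GFP), EndoA 3R 18907675 (64.9%) and Vha16-1 2R 6625851 (5.11%) were each lower in 4 lines. In Adar_VDRC7763 they read 3.92%, 6.97% and 0.159%.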
